A study of Mus musculus with 14 samples.

How the data were processed

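Counts of 20-base signature tags were measured in 14 mouse libraries, 1 female and 1 male library from each of 7 tissues: bone marrow, hippocampus, liver, pancreas, parotid gland, spinal cord and stomach. Per the labels, total RNA of C57BL6 mice was turned into cDNA, cut with DpnII and captured with MmeI, so that each transcript is represented by the bases that follow a GATC site near its 3′ end. The deposited values are raw counts, 1 count per sequenced copy of a distinct tag, with no normalization. The authors assigned tags to UniGene clusters, mitochondrial genes, genome positions or repeats and gave each a class code. The aligner, the genome build and the UniGene build are not given in the sources used here, and no coordinates were used.

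The files held 45337175 counts of 1538190 distinct tags. Library totals ran from 2194028 to 3834568 counts. Class codes 1 to 4 were taken as tags on the sense strand of a transcript, and codes 11 to 16 as their counterparts on the reverse strand. The legend of the codes is not given, and this reading is an assumption. Each of 13 mitochondrial genes had 1 tag of code 4 and 1 of code 14, which shows counterparts but not which strand is sense. Code 4 had more counts than code 14 in 11 of them, and fewer in COX3 (424 against 8419) and ND6 (1077 against 13527). Counts of codes 1 to 4 were summed per UniGene cluster, mitochondrial genes included, which gave 22039 genes. Gene symbols come from the accession or title that the files give, and 8366 genes, with 12.3% of the gene counts, are known by their title only. Tags from other positions of a transcript, from the reverse strand, from genome positions without a gene and without any assignment were left out of the gene tests and are described as shares of a library.

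Levels are CPM, counts scaled to the depth of the counts assigned to genes, given as mean ± SD over the 2 libraries of a tissue (n = 2). At these depths a count of 0 allows up to 3 counts, which is 1.099 CPM in the female bone marrow library. The exact (Clopper-Pearson) 95% intervals of single-library shares cover counting error only. The labels do not say how many animals stand behind a library, so the p-values of the gene tests rest on the spread between these libraries. With 1 library per tissue and sex, that spread also holds any sex difference that varies between tissues.

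Gene tests used edgeR 4.0.16 in R 4.3.3, with TMM scaling, filterByExpr by tissue, which kept 14613 genes, and quasi-likelihood F tests. A shared fit with terms for tissue and sex left 6 residual degrees of freedom. In it each tissue was set against the mean of the other 6, hippocampus against spinal cord, pancreas against parotid, and male against female over the 7 pairs. A sex difference within 1 tissue was tested in a fit with a sex term of its own for that tissue and 5 residual degrees of freedom. Because a tissue has 1 library per sex, that pair was assumed to vary like the other 6 pairs, and nothing checks this within a tissue. The difference between the fold in that tissue and the fold in the other 6 was tested in the same fit. Calls needed a Benjamini-Hochberg adjusted p under 0.05 and a fold of at least 2, with no minimum fold for the sex difference over 7 tissues. Fold changes are log2 ± standard error. The comparison with the mean of the other 6 tissues weights the fitted log level of each tissue equally, so a gene absent from several tissues can pass at a low level. For a gene with 0 counts in a tissue the fitted fold depends on the prior count, and levels are given instead.

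There were 41 gene lists with 611 genes, and those with at least 3 tested members were tested with camera in limma 3.58.1 on voom values at a preset correlation of 0.01, adjusted over the lists of a comparison. The same test was run with an estimated correlation, and fry was run beside it. Libraries were compared by Spearman correlation over genes of log2(CPM + 1). The scale of tag GC content counts the G and C bases after GATC in the most abundant tag of a gene. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 did the tables and figures. Some genes are withheld for evaluation and not reported here.

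Named genes follow a rule fixed, like the comparisons, the tests, the lists and most of the other settings, before the data were examined. For a tissue against the others, they are the 8 genes with the highest mean CPM among those called higher whose 2 libraries lie above all 12 others, and from each list that fits the tissue up to 4 members with the smallest adjusted p. For sex over 7 tissues they are up to 10 called genes per direction with the smallest p and the same direction in at least 6 tissues, and every tested gene that is Y-linked or escapes X inactivation. For sex in 1 tissue they are up to 6 called genes per direction, and in liver and parotid up to 6 members of each of 3 lists with a known sex difference. For the 2 tissue pairs they are up to 10 called genes per direction with the largest fold and at least 50 CPM in 1 tissue. As examples of other cell types, the 3 members with the highest CPM are named. Genes named outside this rule are marked as chosen after their values were seen.

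The other settings fixed then were DESeq2 size factors, library totals without a composition factor, DESeq2 1.42.0, limma voom, no filter, a stricter filter of 10 CPM in 2 libraries, other sets of tags, models without a tissue or sex term, fits on fewer tissues and leaving out each library in turn. The procedure was tested on simulated data made from these libraries. In them the changed genes were drawn among those with higher counts, and no minimum fold was applied. For liver against the other tissues, all tissues were given the same base level. Of such genes 83.3% with a 4-fold change in liver against the other tissues and 97.0% with a 4-fold sex difference over 7 tissues were recovered, against 13.6% with a 4-fold sex difference within liver. These rates do not describe genes with few counts. Of the unchanged genes 5, 14 and 4 were called in these 3 tests, so single calls between the sexes can be false.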

Results

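The series measured transcript signatures in 7 tissues of male and female mice, with 14 libraries in all, 1 per tissue and sex. Its labels give the tissue and sex of each library and name a transcriptome project, without a stated hypothesis. The liver titles name the right lobe for the female and the left lobe for the male library, but both library codes end in LL. A difference in lobe, if there was one, cannot be told apart from sex. Female and male libraries held 3309760 and 3476959 counts in bone marrow, 3460719 and 3557180 in hippocampus, 2466184 and 3794733 in liver, and 3003859 and 2915699 in pancreas. They held 3792260 and 3834568 counts in parotid, 3367093 and 3024038 in spinal cord, and 3140095 and 2194028 in stomach. In the accounts of gene lists, the number that passed adjusted over the list alone equals the number adjusted over all genes unless both are given. Where 2 adjusted p-values of camera follow a list as a pair, the first is with the preset and the second with an estimated correlation.

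The glands put most of their transcripts into a few secreted proteins. In pancreas, the 10 most abundant genes took 73.5% ± 0.790 (SD, n = 2) of all counts, led by the pancreatic amylase Amy2a. In parotid the 10 most abundant took 69.2% ± 0.323, led by the salivary protein Bpifa2. In spinal cord they took 12.7% ± 1.97 and in hippocampus 15.1% ± 0.178. Mitochondrial genes took 14.1% of counts in hippocampus and 0.723% in pancreas. Tags read as sense transcripts took 91.5% ± 0.806 of all counts in pancreas, 69.8% in hippocampus and 65.0% ± 5.90 in spinal cord. In stomach, 73.5% of the female and 87.6% of the male library were assigned to genes.

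Each library was nearest to the other library of its own tissue. The 7 same-tissue pairs had a mean Spearman correlation over genes of 0.926 (SD 0.0725), lowest in stomach at 0.814 and pancreas at 0.827, and highest in hippocampus at 0.979. The 84 pairs of different tissues lay between 0.373 and 0.901, and hippocampus with spinal cord made the highest of them. All 14 libraries had their own tissue as nearest neighbour, and among 135135 ways to pair the libraries none had a higher mean (exact permutation test, one-sided p = 7.4e-06, the smallest it can give). These correlations are across genes, which are not independent replicates.

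**Figure D1:**
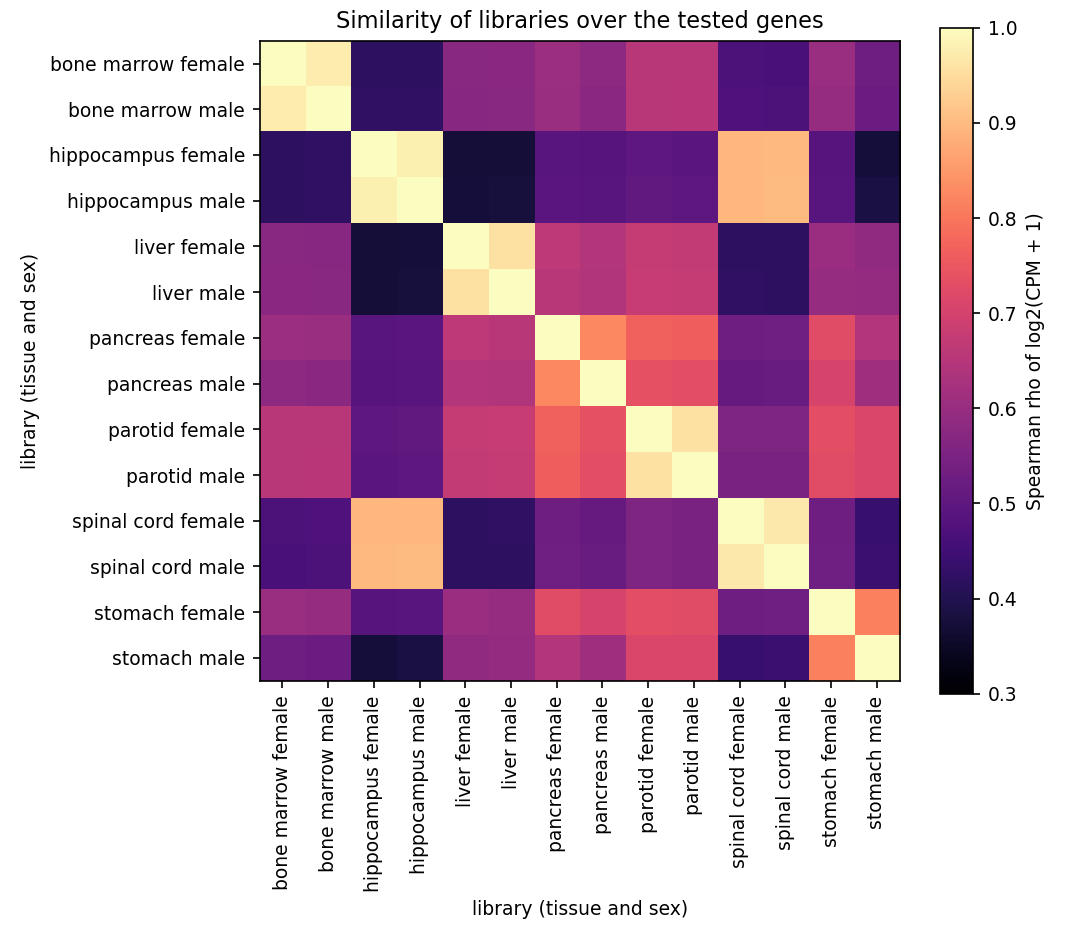
Spearman correlation over genes of log2(CPM + 1) between every pair of the 14 libraries, with tissue and sex on both axes and the correlation as colour. Same-tissue pairs lie between 0.814 and 0.979, while the closest pair of different tissues, hippocampus and spinal cord, reaches 0.901.

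Bone marrow was set apart by the transcripts of developing blood cells. The beta globin genes Hbb-b1/Hbb-b2 stood at 239509.6 ± 12662 CPM (SD, n = 2) against 4473 ± 80.3 in spinal cord, the next tissue, and were higher than the mean of the other tissues by 8.42 ± 0.34 on the log2 scale. The alpha globin Hba-a1 reached 118752 ± 3692 CPM. Granulocyte products followed: Ngp, a neutrophil granule protein, at 11255 ± 2127 CPM, and the calcium-binding S100a9 at 10342 ± 676. The eosinophil ribonucleases Ear1/Ear2 stood at 6684 ± 1856, and the lysozyme Lyz2 at 5853 ± 375. Genes titled ribosomal protein S23 (Gm5148, 7786 ± 733 CPM) and S29 (Mm.379006, 5420.3 ± 709) completed the most abundant leading genes. All 17 tested neutrophil granule genes rose (camera adjusted p = 4.84e-19, and adjusted p = 0.0295 with an estimated correlation). Among them were the gelatinase Mmp9 at 254 ± 23.1 CPM and cathepsin G, Ctsg, at 490.3 ± 38.0. The 17 tested erythroid genes rose as well (1.48e-18, and adjusted p = 0.00779 with an estimated correlation), with Trim10 at 1119 ± 19.3 CPM and the nuclear protein Hemgn at 531 ± 64.7. So did 13 of 13 B lineage genes (8.39e-09 and 0.0295). They included the antigen receptor chains Cd79b (448 ± 28.1 CPM) and Cd79a (294 ± 57.6), and Vpreb3 (247 ± 15.7). Proliferation genes rose in 21 of 21 cases (2.84e-16 and 0.0172). The nucleotide reductase subunit Rrm2 stood at 943 ± 30.5 CPM, the proliferation antigen Mki67 at 453 ± 11.8, survivin, Birc5, at 177 ± 13.9 and the replicative helicase subunit Mcm2 at 91.6 ± 8.37. The T and natural killer cell genes rose in 7 of 7 cases and macrophage genes in 9 of 12 (both 0.000612, but adjusted p = 0.0888 with an estimated correlation for each). In edgeR, 4977 of 14613 genes passed, 2874 higher and 2103 lower, and 1778 of the higher genes lay above every other library in both marrow libraries. With library totals in place of TMM the split was 4636 higher and 1246 lower, and the median of all genes moved from −0.20 to 0.37. The balance reversed in limma voom, with 2732 higher and 4860 lower, and in DESeq2, with 2623 and 3050.

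Hippocampus carried transcripts of synapses and of excitatory neurons. Among its leading genes were the neuronal protein neurochondrin, Ncdn, at 3658 ± 238 CPM (SD, n = 2) against 1364 ± 99.5 in spinal cord (log2 5.97 ± 0.25 over the mean of the other tissues), Itm2c at 3542 ± 84.8, and Atp1b1, a subunit of the sodium pump, at 3271 ± 28.6. The mitochondrial gene mt-Nd1, a complex I subunit, stood at 44513 ± 3238 CPM against 40866 ± 1002 in spinal cord, and the mitochondrial 16S ribosomal RNA at 3679 ± 168. The glycolytic enzymes Pgam1 (3324 ± 213 CPM) and Pgk1 (3129.5 ± 254) and the cytochrome c oxidase subunit Mm.14022 (3539 ± 80.02) were also among the highest. All 19 synaptic genes tested rose (camera adjusted p = 3.63e-13, and adjusted p = 0.00945 with an estimated correlation). They included the vesicle fusion protein Snap25 (1164 ± 3.45 CPM), the synapsin Syn1 (546 ± 2.46) and Rtn1 (2223 ± 50.7). Snap25 was no lower in spinal cord, at 1336 ± 87.6 CPM. The 22 excitatory neuron genes rose too (1.57e-13 and 0.00537). Crym, a thyroid hormone binding protein, stood at 916 ± 31.5 CPM against 2.90 ± 0.0430 in spinal cord, the inositol trisphosphate kinase Itpka at 629.8 ± 5.36 against 10.7 ± 6.99 in stomach, and Cbx6/Npcd/Nptxr at 1663 ± 134 against 280.4 ± 15.8 (log2 5.17 ± 0.24). Of 12 astrocyte genes 10 rose (0.000863 and 0.0350). These were among others the glutamate transporters Slc1a2 (1277 ± 58.2 CPM) and Slc1a3 (314 ± 14.9), the aldolase Aldoc (818 ± 6.51) and the filament protein Gfap (301 ± 19.2), the last 2 lower than in spinal cord. Myelin genes rose in 15 of 18 cases (1.79e-06 and 0.0288). Proliferation genes fell in 11 of 21 cases (6.66e-06 and 0.0438). Their summed level, 116.3 CPM in the female and 104.8 in the male library, was nevertheless above that in liver, pancreas and parotid. The mean of the other tissues includes bone marrow, at 3723 and 4042 CPM. In edgeR 5971 genes passed, 4086 higher and 1885 lower. With library totals the split was 8705 higher and 471 lower, 435 of the 5971 genes changed sign, and the median of all genes moved from 0.15 to 1.46.

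Liver was marked by plasma proteins and by the enzymes of nitrogen, bile acid and glucose metabolism. The major urinary protein Mup1 stood at 124415 ± 102187 CPM (SD, n = 2) against 149 ± 79.3 in stomach, a spread between its 2 libraries nearly as large as the mean. Albumin, Alb, reached 38344 ± 10937 CPM and the protease inhibitor Mm.312593 (serine peptidase inhibitor clade A) 33655 ± 9588. The apolipoproteins Apoa1 and Apoe reached 16112 ± 4434 and 13329.6 ± 1268 CPM, the cytochrome Cyp2e1 10446 ± 7557, Mup3 8989 ± 4714 and Mup20 8642 ± 11675. All 21 plasma protein genes tested rose (camera adjusted p = 1.96e-24, and adjusted p = 0.00465 with an estimated correlation). Apoc3 stood at 4472 ± 2183 CPM, antithrombin, Serpinc1, at 2232 ± 565 (log2 8.93 ± 0.26), the heme carrier Hpx at 3839 ± 11.6 and the fibrinogen chain Fgg at 2071 ± 465. The 7 urea cycle genes rose (1.39e-08, but adjusted p = 0.0524 with an estimated correlation), with Ass1 at 1464 ± 97.48 CPM, Asl at 669 ± 24.7 (log2 5.64 ± 0.23), Otc at 481 ± 22.9 and the ornithine carrier Slc25a15 at 299 ± 68.2. Bile acid genes rose in 10 of 10 cases (7.30e-12 and 0.00465). Among them were the acyl-CoA synthetase Slc27a5 (1209 ± 468 CPM), the hydroxylase Cyp27a1 (521 ± 7.03), the dehydrogenase Hsd3b7 (283 ± 86.2) and the bile salt export pump Abcb11 (259.6 ± 72.9 against 0.693 ± 0.245 in stomach). The 13 genes of gluconeogenesis and amino acid breakdown rose (1.74e-16 and 0.00465). They included the tryptophan dioxygenase Tdo2 (2572 ± 384 CPM) and Fbp1 (703 ± 50.4). Of 4175 genes passing in edgeR, 2695 were higher and 1480 lower. DESeq2 called 2320 higher and 2359 lower, limma voom 2569 and 4166, and DESeq2 size factors in the same edgeR fit moved the median of all genes from −0.16 to −0.26.

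Pancreas was dominated by the enzymes that acinar cells secrete. Amylase, Amy2a, stood at 295152 ± 68359 CPM (SD, n = 2) against 1567 ± 805 in stomach. The proteases chymotrypsinogen, Ctrb1, and trypsinogen, Prss2, stood at 146198 ± 36759 and 97525 ± 16814, and Try5 at 68089 ± 4347. The elastase and chymotrypsin Cela2a/Ctrc stood at 47387 ± 1287, the lipase Pnlip at 35979 ± 3219.7, 2210010C04Rik at 33770.3 ± 3021 and Ctrl at 25307 ± 2835. All 24 digestive enzyme genes tested rose (camera adjusted p = 4.39e-51, and adjusted p = 0.0313 with an estimated correlation). Among them were the bile salt-stimulated lipase Cel (16693 ± 261 CPM), Sycn of the zymogen granule (14635 ± 1759.7), carboxypeptidase Cpb1 (11081 ± 767) and elastase Cela1 (10208 ± 992, log2 13.87 ± 0.40). The 3 Reg family genes rose (3.70e-06, but adjusted p = 0.0664 with an estimated correlation), with Reg1 at 11231 ± 7859 CPM, Reg2 at 480.0 ± 664 and Reg3d at 175 ± 91.6. The 5 acinar transcription factor genes rose (3.47e-07 and 0.0313). Of these Rbpjl stood at 46.2 ± 11.9 CPM against 3.81 ± 0.491 in stomach, while Bhlha15 (47.0 ± 13.7), Xbp1 (269 ± 17.2) and Gata4 (2.01 ± 1.25) were each more abundant in another tissue. Islet genes rose in 9 of 12 cases, and in 12 adjusted over the list alone (3.85e-08 and 0.0345). The amyloid peptide Iapp stood at 79.6 ± 1.07 CPM, glucagon, Gcg, at 95.6 ± 60.1, and G6pc2 at 5.95 ± 2.79 with 0 counts in every other library. Scg2 stood at 3.13 ± 0.167 against 149 ± 8.03 in spinal cord. Duct genes split, 4 higher and 1 lower of 8 (0.0369, but adjusted p = 0.133 with an estimated correlation), with Muc1 at 18.5 ± 1.60 CPM and Ambp at 2.05 ± 1.37. Spp1, at 21.3 ± 6.67 CPM, was higher by 2.23 ± 0.37 under TMM and lower, at −0.81, with library totals. In edgeR 1403 genes passed, 927 higher and 476 lower. The count was 570 without the female pancreas library, 607 without the male one and 2202 without the female stomach library. With library totals 193 were higher and 10405 lower, the median of all genes moved from −0.59 to −3.26, and 581 of the 1403 genes changed sign.

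**Figure D2:**
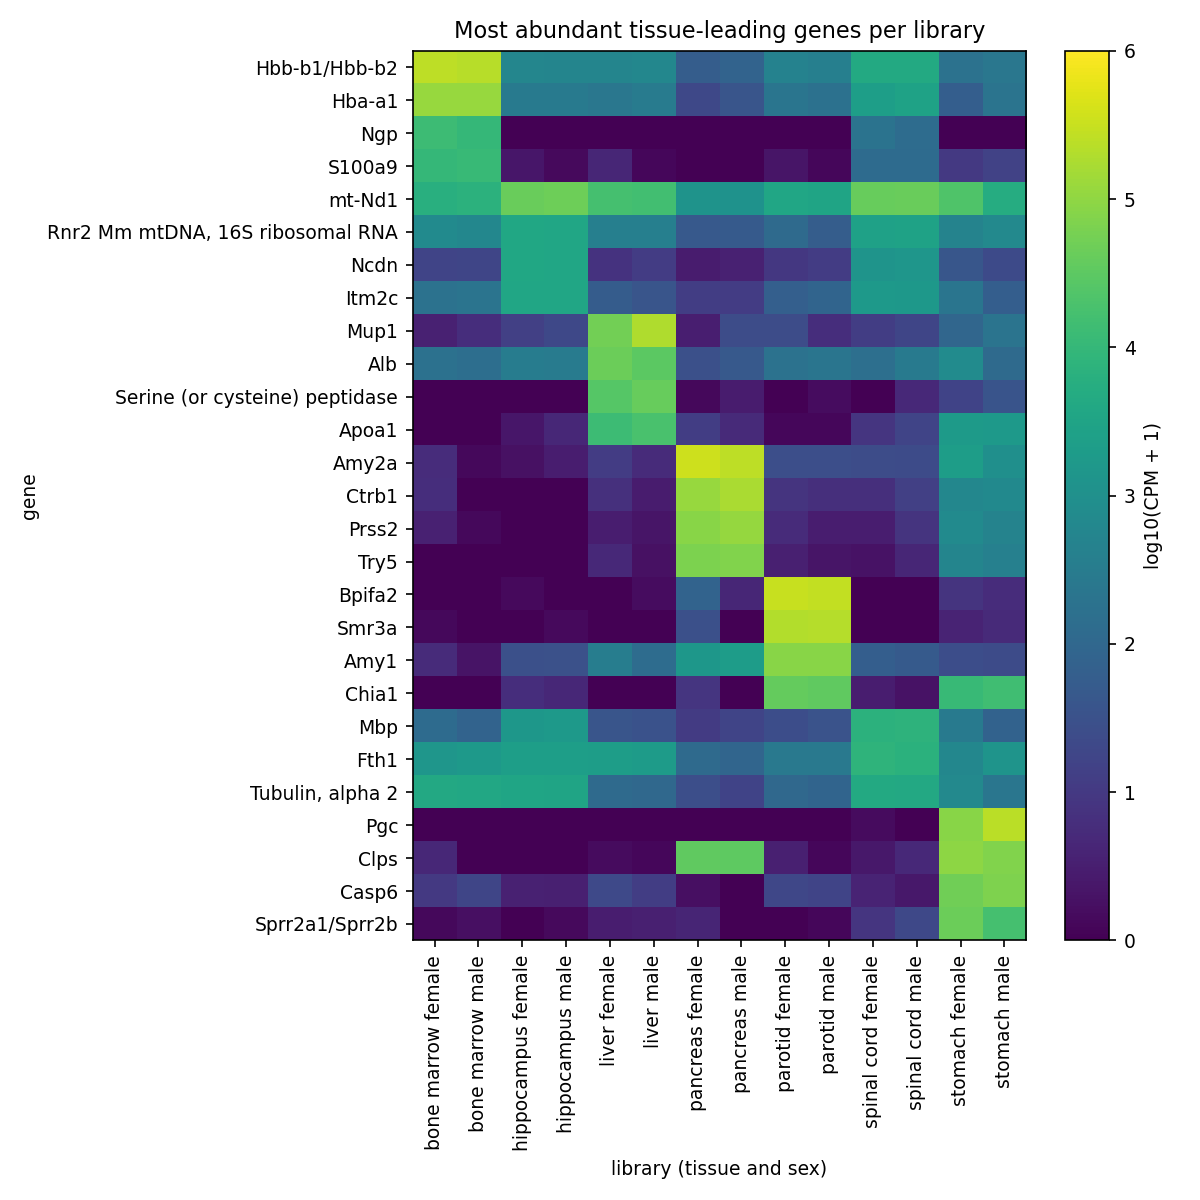
Levels of leading genes among the 4 most abundant of each tissue in the 14 libraries, as log10(CPM + 1). Each block, of 3 genes for spinal cord and 4 for the other tissues, is highest in its own tissue, from Amy2a at 295152 CPM in pancreas and Bpifa2 at 297593 in parotid to neurochondrin, Ncdn, at 3658 in hippocampus.

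Parotid was dominated by salivary proteins. Bpifa2, the parotid secretory protein, stood at 297593 ± 17968 CPM (SD, n = 2) against 41.3 ± 53.6 in pancreas, and Smr3a at 212852 ± 6449.7. Salivary amylase, Amy1, reached 87286 ± 467 CPM (log2 11.51 ± 0.41) and the chitinase Chia1 36122 ± 3587 against 12759.6 ± 2418 in stomach. Further leading genes were BC037156 at 33699 ± 1936 CPM, the carbonic anhydrase Car6 at 25843 ± 2078, Pip at 24131 ± 4986 and 2310057J18Rik at 22998 ± 2899. All 17 parotid secretory genes tested rose (camera adjusted p = 1.74e-35, and adjusted p = 0.00190 with an estimated correlation). They included the nuclease Dnase1 (12926 ± 1669 CPM) and the potassium channel Kcnn4 (161 ± 9.36). The 3 granular duct genes tested rose (1.83e-05, but adjusted p = 0.0593 with an estimated correlation), with epidermal growth factor, Egf, at 50.7 ± 1.84 CPM. The kallikreins Klk1 (2668 ± 371 CPM) and Klk1b24 (4.64 ± 2.43) were higher in pancreas, at 7341 ± 317 and 33.4 ± 9.35. Genes of other cell types moved with the tissue. These were 11 of 11 skeletal muscle genes (2.00e-11, but adjusted p = 0.101 with an estimated correlation), whose summed level was 326.8 CPM in the female and 425.0 in the male library, and 9 of 9 adipose genes (8.04e-09 and 0.0451), at 1121 and 572 CPM. Of 23 genes of the endoplasmic reticulum 10 rose and 0 fell, 10 and 2 adjusted over the list alone (0.0149, but adjusted p = 0.142 with an estimated correlation), such as Sec61b (174 ± 10.9 CPM), Sec61a1 (89.8 ± 5.43), the signal peptidase subunit Spcs2 (46.9 ± 2.70) and Dnajc3 (105 ± 11.1). Their median fold turned to −0.51 with library totals. Counted by edgeR, 2188 genes passed, 1622 higher and 566 lower, and refits gave 1061 without the female parotid library and 1005 without the male one. The split became 747 higher and 3487 lower with library totals, where the median of all genes moved from −0.02 to −1.03, and 1544 higher and 2290 lower in limma voom.

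Spinal cord was rich in myelin, in neurofilaments and in genes of body axis position. The myelin protein Mbp stood at 7385 ± 425 CPM (SD, n = 2), against 1585 ± 81.9 in hippocampus (log2 4.93 ± 0.30 over the mean of the other tissues). Ferritin heavy chain, Fth1, reached 7296 ± 861 CPM. Neurofilament Nefm stood at 3278 ± 243 CPM, the tubulin Mm.379036 at 4366 ± 135, the GNAS cluster Mm.125770 at 3554 ± 291, and Mm.380801, titled interleukin 31 receptor A, at 2925 ± 222. All 18 myelin genes tested rose (camera adjusted p = 1.42e-12, and adjusted p = 0.0125 with an estimated correlation), with Cldn11 at 1176 ± 100.3 CPM, Mobp at 1195 ± 31.5 and the galactolipid enzyme Ugt8a at 346 ± 55.4. The 19 Hox genes tested rose (6.81e-12 and 0.0170). Among them were Hoxc4 (104 ± 15.6 CPM), Hoxd8 (82.7 ± 8.75), Hoxb6 (65.9 ± 3.46) and Hoxa7 (63.3 ± 6.42). Of 12 motor neuron and cholinergic genes 11 rose (1.24e-07 and 0.0223). They included the neurofilaments Nefl (2896 ± 224 CPM) and Nefh (236 ± 103) and the peptide gene Calca (67.4 ± 2.72 against 0.606 ± 0.261 in hippocampus). The 7 glycine and GABA genes rose (1.22e-06 and 0.0262). The glycine transporter Slc6a5 stood at 200.4 ± 52.2 CPM against 0.408 ± 0.0180 in hippocampus, and Glrb at 238 ± 60.6. The GABA-synthesizing Gad2 (209.8 ± 14.3 CPM) and Gad1 (116 ± 1.74) were both lower than in hippocampus. Astrocyte genes rose in 11 of 12 cases (1.86e-06 and 0.0170), and synaptic genes in 17 of 19, or 18 adjusted over the list alone (6.81e-12 and 0.0161). Markers of other tissues moved with spinal cord. Skeletal muscle genes rose in 10 of 11 cases (0.000695, but adjusted p = 0.316 with an estimated correlation), led by Pvalb (149 ± 20.7 CPM), which some neurons also express, and by Tnnc2 (122 ± 80.5) and Myh4 (87.5 ± 60.9). In addition 9 of 17 neutrophil granule genes and 9 of 17 erythroid genes were also called higher, without the lists passing (camera adjusted p = 0.213 and 0.203). In edgeR 5250 genes passed, 3981 higher and 1269 lower. With library totals the split was 9816 higher and 156 lower, 494 of the 5250 genes changed sign, and the median of all genes moved from 0.25 to 1.69.

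Stomach combined gastric glands, smooth muscle and a stratified epithelium. The pepsinogen Pgc stood at 159277 ± 105759 CPM (SD, n = 2), with 1 count in all other libraries together. The cornified envelope genes Sprr2a1/Sprr2b reached 30859 ± 18954 CPM, the mucosal peptide Gkn2 20112 ± 7375, the trefoil peptide Tff2 6357 ± 295 against 1867 ± 135 in pancreas, and the fatty acid binding protein Fabp5 4255 ± 4356. A tag assigned to Casp6, an assignment that rests on an expressed sequence tag and was not checked, had 59051 ± 13788 CPM. All 21 gastric gland genes tested rose (camera adjusted p = 1.40e-30, and adjusted p = 0.00246 with an estimated correlation). They included the mucin Muc5ac (3252 ± 339.9 CPM), the proton pump subunit Atp4a (2203 ± 1464) and the protease Ctse (1239 ± 529.6, log2 5.56 ± 0.23). The 13 smooth muscle genes rose (6.15e-16 and 0.00246). The actins Actg2 and Acta2 stood at 3612 ± 4028 and 2773 ± 1015 CPM (log2 6.98 ± 0.23 for Acta2), the myosin Myh11 at 581 ± 167 and desmin, Des, at 535 ± 490.1. The 12 genes of stratified squamous epithelium rose (5.06e-14 and 0.0123). Loricrin, Lor, stood at 1348 ± 763 CPM, keratin Krt4 at 1122 ± 671, Sprr3 at 339 ± 128 with 0 counts elsewhere, and Sprr1a at 307 ± 154. Of 6 endocrine genes 5 rose (0.000231, but adjusted p = 0.0750 with an estimated correlation). They were ghrelin, Ghrl, at 1992 ± 32.5 CPM, and others, each more abundant in hippocampus or spinal cord, such as somatostatin, Sst (200.2 ± 42.8), Chga (95.2 ± 54.4) and Chgb (26.1 ± 9.38). Genes of pancreatic enzymes also rose, 20 of 24 and 21 adjusted over the list alone (7.84e-15, but adjusted p = 0.107 with an estimated correlation). Of these the lipase cofactor Clps stood at 83888 ± 13423 CPM against 33606 ± 2129.9 in pancreas and the phospholipase Pla2g1b at 19826 ± 13593 against 594 ± 26.6. Skeletal muscle genes rose in 8 of 11 cases, 10 adjusted over the list alone (0.0332, but adjusted p = 0.578 with an estimated correlation), at a summed 64.6 CPM in the female and 403.6 in the male library. In edgeR 3208 genes passed, 2630 higher and 578 lower, and 5098 passed without the female stomach library. Under library totals 3969 were higher and 204 lower, the median of all genes moved from 0.17 to 0.53, and limma voom split them 2105 to 2140.

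Hippocampus and spinal cord, the most similar tissues, differed in forebrain, choroid plexus and spinal genes. Transthyretin, Ttr, a product of the choroid plexus, stood at 4897 ± 2389 CPM in hippocampus and 0.956 ± 1.35 in spinal cord (SD, n = 2; log2 12.27 ± 0.81, adjusted p = 1.30e-07). Crym was higher by 8.38 ± 0.71, the tyrosine kinase Ptk2b (730.4 ± 87.4 against 8.21 ± 1.24 CPM) by 6.59 ± 0.69, the muscarinic receptor Chrm1 (113 ± 16.6 against 1.22 ± 1.73) by 6.58 ± 0.69 and Itpka by 6.09 ± 0.56. Spink8 (153 ± 8.55 CPM), the potassium channel Kcnh3 (71.0 ± 0.294), the adhesion molecule Icam5 (55.2 ± 4.77), the exchanger Slc9a4 (53.9 ± 8.85) and the choroid plexus channel Clic6 (53.9 ± 23.3) were below 1 CPM in spinal cord. On the spinal side, Slc6a5 stood at 200.4 ± 52.2 CPM. The Hox genes Hoxd8, Hoxb6, Hoxa7, Hoxc6 (53.3 ± 11.8 CPM), Hoxb5 (51.6 ± 16.3) and Hoxb7 (50.7 ± 4.03) had 0 counts in hippocampus, and Hoxc4 had 0.211 ± 0.298 CPM. Excitatory neuron genes were higher in hippocampus in 18 of 22 cases, 21 adjusted over the list alone (camera adjusted p = 6.17e-31 and 0.000517). Lower in hippocampus were all 19 Hox genes (2.21e-42 and 0.00195), 9 of 12 motor neuron genes, 10 adjusted over the list alone (1.36e-14 and 0.00828), and 10 of 18 myelin genes, 15 adjusted over the list alone (1.48e-13 and 0.00307). Transcripts of marrow and muscle moved with them. Of these, 11 of 17 neutrophil granule genes were lower in hippocampus, 15 adjusted over the list alone (4.30e-21 and 0.0110), such as Ngp at 0 against 164 ± 44.5 CPM. So were 9 of 17 erythroid genes, 11 adjusted over the list alone (4.58e-13 and 0.00775), and 10 of 11 skeletal muscle genes, 11 adjusted over the list alone (4.17e-14, but adjusted p = 0.0902 with an estimated correlation). In edgeR 941 genes passed, 479 higher and 462 lower in hippocampus, while library totals gave 408 and 521. The count was 2202 without the stomach pair, 2225 and 2230 without its female or male library. It was 321 and 311 without the female or male hippocampus library, and 300 and 321 without the female or male spinal cord library.

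Pancreas and parotid, both exocrine glands, differed in enzymes and salivary proteins. In pancreas Pnlip stood at 35979 ± 3219.7 CPM against 1.02 ± 0.214 in parotid (SD, n = 2; log2 16.89 ± 1.21, adjusted p = 4.25e-08), and Try5, Prss2, Ctrb1 and Clps were higher by 17.04 ± 1.31, 16.72 ± 1.39, 16.33 ± 1.56 and 16.50 ± 1.36. Tff2 (1867 ± 135 CPM), Mm.272, a Kazal-type trypsin inhibitor (867 ± 92.7), the disulfide isomerase Pdia2 (635 ± 113) and the lipase Pnliprp2 (494 ± 67.2) had 0 counts in parotid, and Reg1 had 1. In parotid the androgen binding protein Mm.358887 (2665 ± 259.8 CPM), Crisp1 (2534 ± 16.1), the antimicrobial Wfdc12 (1712 ± 1024), lactoperoxidase, Lpo (859 ± 123), the proline-rich Prpmp5 (448 ± 14.6), Gm4736 (407 ± 7.13), angiotensinogen, Agt (259 ± 40.2), Mm.156682 (237 ± 17.6) and the odorant binding protein-like Mm.56921 (155 ± 204) had 0 counts in pancreas. Smr3a had 13.9 ± 19.7 CPM. All 24 enzyme genes were higher in pancreas (camera adjusted p = 1.28e-37, and adjusted p = 0.0418 with an estimated correlation), with 9 of 12 islet genes, 11 adjusted over the list alone (2.13e-10 and 0.0418), and 3 of 5 acinar factors, 4 adjusted over the list alone (0.000539 and 0.0444). All 17 parotid secretory genes were higher in parotid (1.85e-28 and 0.00369), as were 9 of 11 skeletal muscle genes, 10 adjusted over the list alone (1.36e-09, but adjusted p = 0.137 with an estimated correlation). In edgeR 927 genes passed, 417 higher in pancreas and 510 in parotid. The count was 1815 without the stomach pair, 1868 and 1867 without its female or male library. It was 444 and 439 without the female or male pancreas library, 462 and 537 without the female or male parotid library. With library totals 221 were higher and 6813 lower in pancreas, where the median of all genes moved from −0.24 to −1.96. The balance was the opposite in limma voom (2294 higher and 1112 lower), in DESeq2 (548 and 345) and with DESeq2 size factors (491 and 422).

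Over all 7 pairs, few genes passed between male and female with the stomach pair in the fit, and Y-linked genes led them. A low count of calls does not show that few genes differ. Ddx3y, an RNA helicase on the Y chromosome, had 0 counts in all 7 female libraries and 15 to 186 in the male ones, with 37.0 ± 31.5 CPM in males (SD, n = 7; adjusted p = 3.80e-06). The translation factor gene Eif2s3y stood at 11.1 ± 5.98 CPM in males against 0.0600 ± 0.159 in females, higher in 7 of 7 tissues (3.80e-06). The demethylase Kdm5d stood at 4.93 ± 3.37 against 0.0600 ± 0.159, higher in 6 tissues with 0 counts in both pancreas libraries (0.000545). The male libraries alone held Mm.385427, an unclassified thymus cDNA (15.5 ± 16.7 CPM, adjusted p = 0.000167), and Mm.380197, without a title (3.12 ± 2.53, adjusted p = 0.0400). Xist, the RNA that silences an X chromosome, fell by 5.28 ± 0.88 on the log2 scale (adjusted p = 0.0226), with more counts in the female library in 6 of 7 tissues. The exception was pancreas, where 1 tag, GATCTCCCCCTCCGTGCATC, had 361 counts in the female and 554 in the male library. Without that tag, Xist had 9 to 231 counts in female and 0 or 1 in male libraries. Its fold over 7 tissues turned positive, to 0.58, when only the most abundant tag of each gene was counted. Of the 10 tested genes listed as escaping X inactivation, a list that includes Xist, only Xist passed, and 3 passed adjusted over the list alone (camera adjusted p = 3.25e-05, but adjusted p = 0.0541 with an estimated correlation). Eif2s3x, with 54.1 ± 27.3 CPM in females and 32.2 ± 19.1 in males, and Kdm6a, with 34.7 ± 21.4 and 19.3 ± 16.6, were higher in females in 7 of 7 tissues without passing over all genes (adjusted p = 0.621 and 0.567). Ddx3x and Ftx were also higher in 7 of 7 female libraries (log2 −0.36 ± 0.20 and −0.67 ± 0.29), and Kdm5c, Jpx, Pbdc1, Usp9x and 5530601H04Rik lay between −0.77 and 0.17. In addition, 3 genes chosen after their values were seen passed because of 1 tissue. These were the urinary protein Mup20 with 779 and 55883 counts in female and male liver, Reg2 with 30 and 2517 in pancreas, and Mm.56921 with 1022 and 36 in parotid. In edgeR 9 genes passed, 7 higher in males and 2 in females, from 487 with an unadjusted p under 0.05. DESeq2 called 5 and limma 3, and 83 passed without the stomach pair. Leaving out 1 library gave 118 or 119 for stomach, 33 or 34 for hippocampus, 29 for spinal cord, 18 for pancreas, 16 for parotid and 14 or 15 for bone marrow.

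**Figure D3:**
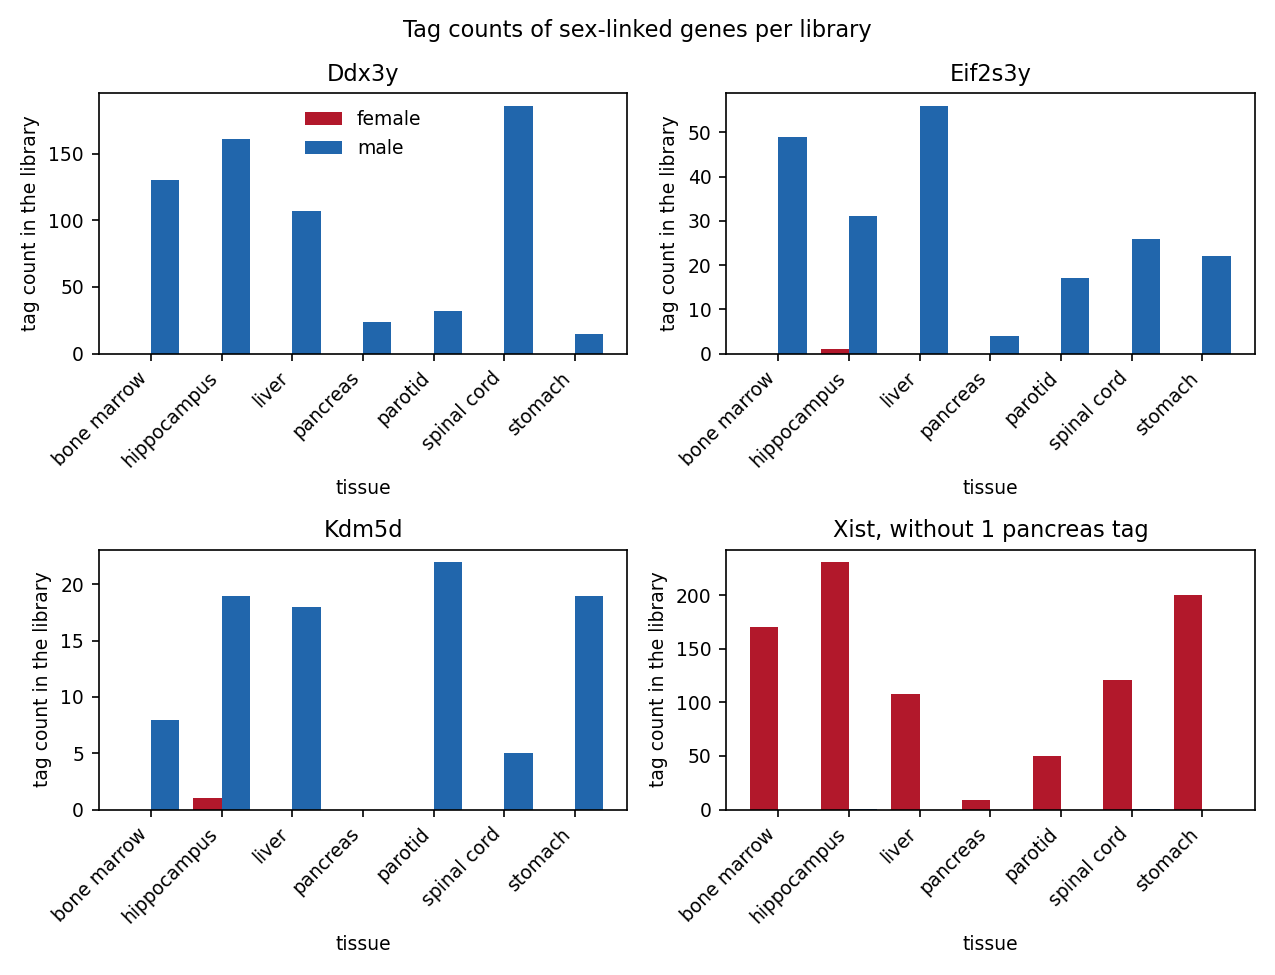
Tag counts per library of the Y-linked genes Ddx3y, Eif2s3y and Kdm5d and of Xist without the tag that was abundant in pancreas, as bars for female and male libraries of each tissue. Ddx3y has 0 counts in every female library and 15 to 186 in the male ones, while Xist has 9 to 231 in the female libraries and 0 or 1 in the male ones.

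Liver differed between its 2 libraries in genes with a known sex difference. The fatty acid elongase Elovl3 stood at 3.97 CPM in the female and 274 in the male library, a log2 fold of 6.48 ± 0.87 (adjusted p = 0.0328 in edgeR). Mup20 stood at 387 and 16898 CPM (5.83 ± 0.76, adjusted p = 0.0328), and Hamp2, a relative of the iron hormone hepcidin, at 906 and 9.68 (−6.16 ± 0.75, adjusted p = 0.0328). Of 14 male-biased liver genes tested 2 rose, and 11 adjusted over the list alone (camera adjusted p = 9.68e-36, and adjusted p = 0.00430 with an estimated correlation). Members below the threshold over all genes included Gstp1/Gstp2/Traf5 (784 and 6429 CPM), the bile acid hydroxylase Cyp7b1 (38.7 and 429), the complement component C6 (20.3 and 292) and the transporter Slco1a1 (17.9 and 146). Of 12 female-biased genes tested 0 passed over all genes, while 6 were lower in the male library adjusted over the list alone (3.38e-14 and 0.00804). Among them Cyp17a1 stood at 228 CPM in the female and 7.26 in the male library, Cyp2a4/Cyp2a5 at 397 and 103, the fatty acid transporter Abcd2 at 43.7 and 2.12, Atp6v0d2 at 30.3 and 0.605, Fmo2 at 15.9 and 1.51, and Prom1 at 4.96 and 0.302. In edgeR 3 genes passed from 397 with an unadjusted p under 0.05. The count was 25 in DESeq2, 8 in limma and 268 in edgeR without the stomach pair. It was 0 at 10 CPM, with code 1 only, without single tags or with the most abundant tag only. Leaving out 1 library gave 282 or 280 for stomach, 26 or 30 for hippocampus, 25 or 26 for spinal cord, 12 for parotid, 11 for bone marrow and 10 for pancreas.

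In parotid no sex difference was detectable in the kallikreins and growth factor of granular ducts. Klk1 stood at 2405.6 CPM in the female and 2930.5 in the male library (log2 0.28 ± 0.86), Egf at 49.4 and 52.0 (0.07 ± 0.62) and Klk1b24 at 2.92 and 6.36 (1.11 ± 0.74), and none of the 3 passed in edgeR. The protease inhibitor gene A2ml1 alone passed, with 1 count in the female and 1268 in the male library (adjusted p = 0.00141), from 140 genes with an unadjusted p under 0.05. Liver genes of both sex-biased lists were low there, from Gstp1/Gstp2/Traf5 at 52.04 and 53.46 CPM, Ntrk2 at 31.6 and 13.9 CPM and Mup1 at 24.3 and 5.20 to Cyp7b1 with 1 and 0 counts, and none passed. Adipose genes had a summed 1121 CPM in the female and 572 in the male library, with 0 of 9 past the threshold (camera adjusted p = 0.00226, but adjusted p = 0.572 with an estimated correlation). DESeq2 and limma each called 2 genes, edgeR without the stomach pair 16. Without 1 library edgeR called 21 or 19 for stomach, 8 for hippocampus, 5 for spinal cord, and 2 for bone marrow, liver or pancreas.

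In the fits with all 14 libraries, bone marrow, hippocampus, pancreas and spinal cord gave almost no calls between their 2 libraries. Ddx3y passed in hippocampus, with 0 counts in the female and 161 in the male library (adjusted p = 0.00445), and in spinal cord, with 0 and 186 (adjusted p = 0.0102). It had 0 and 130 counts in bone marrow and 0 and 24 in pancreas, without passing. DESeq2 and limma called 0 genes in hippocampus and 0 in spinal cord. In bone marrow edgeR called 0 genes, DESeq2 1 and limma 0, with 152 at an unadjusted p under 0.05. In pancreas edgeR called 0, DESeq2 2 and limma 3, with 404 at an unadjusted p under 0.05. Without the stomach pair the counts were 7 in bone marrow, 4 in hippocampus, 7 in pancreas and 13 in spinal cord. Leaving out the female or male stomach library alone gave 7 or 8, 4 or 4, 12 or 9, and 14 or 15, and leaving out any other library gave at most 1, 3, 1 and 2.

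The 2 stomach libraries differed in far more genes than any other pair, though their correlation of 0.814 was close to that of the pancreas pair, 0.827. The calls take their spread from the other pairs, which the stomach pair did not share. The SD of log2 male over female across genes was 1.61 in stomach, against 0.84 in liver, the next highest. Lower in the male library were Itgb5, an integrin chain, at 770 CPM in the female and 24.4 in the male library (log2 −5.11), and the splicing factor Bud31 (441 and 17.2). So were the ribosomal protein L29 gene Mm.304265 (1759.6 and 99.9), the collagen Col5a2 (289 and 12.5), Slc9a4 (578 and 41.1) and Mettl7a1 (459.8 and 27.0). Higher in the male library were the ribosomal protein genes Mm.280083 (L4, 45.5 and 869.7 CPM), Mm.319719 (L13, 88.0 and 1441) and Rpl28 (101 and 933), the coactivator Edf1 (7.37 and 151), the adhesion protein Ctnna1 (10.8 and 165) and the muscle myosin Myh4, with 0 and 105 counts. Skeletal muscle genes rose in 10 of 11 cases (camera adjusted p = 5.90e-06, but adjusted p = 0.674 with an estimated correlation), at 64.6 and 403.6 CPM. Of 10 mitochondrial mRNAs 1 rose and 5 fell, 1 and 7 adjusted over the list alone (0.00541, but adjusted p = 0.674 with an estimated correlation). The folds followed the base composition of the tags. The median log2 fold of male over female ran from −2.06 for genes with at most 3 G or C bases after GATC to 1.53 for those with 13 to 16. The Spearman correlation across 5294 genes, which are not independent replicates, was 0.711. In edgeR 3784 genes passed, 1718 higher and 2066 lower in the male library, against 1972 and 1891 with DESeq2 size factors and 1837 and 1731 with library totals. The count was 2779 in DESeq2, 2602 in limma, and 1814 after the ratio was centred within classes of tag GC content, an alternative chosen after the data were seen.

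**Figure D4:**
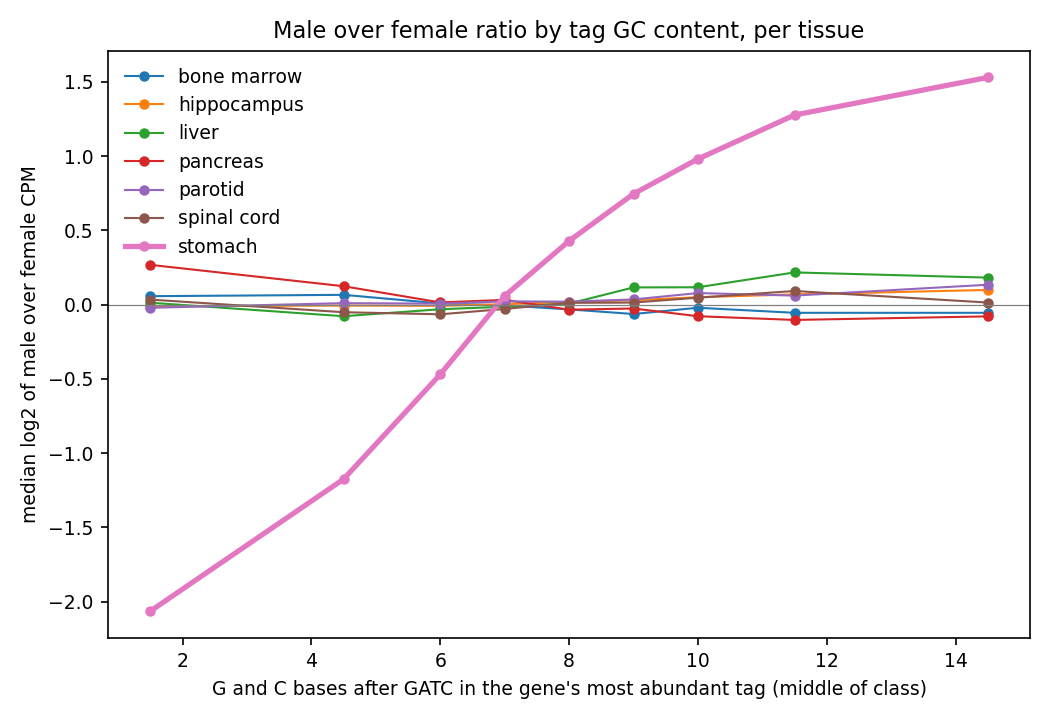
Median log2 ratio of male over female CPM after TMM scaling, among genes grouped by the number of G and C bases after GATC in their most abundant tag. Each tissue has 1 line. The stomach line climbs from −2.06 to 1.53, while the lines of the other 6 tissues stay between −0.10 and 0.27.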

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

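Of the tests below, 3 were chosen only after the result was seen: tag GC content as the whole cause of the stomach difference, pancreatic tissue as the source of Clps and Pla2g1b, and exchange of reads with bone marrow for the muscle transcripts.

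The stomach pair stood out because 3213 genes had a male over female fold that differed from that in the other 6 tissues, against 0 or 1 gene in each of the others (edgeR interaction test), whose fits include the stomach pair in their spread. With the ratio centred on tag GC content, liver gave 17 and the other 5 tissues 0 to 2. A difference in transcript amounts alone, from sex or from the part of the stomach taken, would leave 2 tags of the same gene moving together. Within 1574 genes, however, the ratio rose by 0.487 log2 per G or C base of the tag (95% interval 0.461 to 0.514), which is 1.03 times the slope between genes and forbids that, while no other tissue exceeded 0.0353 in size. A GC-dependent loss of tags in 1 of the 2 libraries may therefore account for the pattern. The male library had a mean of 7.73 G or C bases in its tags of at least 10 counts. The 12 libraries of other tissues had 6.64 to 7.18 and the female one 6.75. Per count, however, its mean of 8.60 was close to the 8.43 and 8.31 of the female and male parotid libraries. Tags with a run of 10 A took 3.91% of the female stomach library, 0.870% of the male one and 1.84% of male hippocampus, the next highest. Which of the 2 stomach libraries departs is therefore not settled. The number of calls after centring on tag GC content was 47.9% of that before. This cannot tell whether tag GC content is the whole cause, because centring removes only the median of each class of tags. A difference between the sexes or between parts of the stomach stays open beside it, untested.

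Transcripts of pancreatic digestive enzymes in stomach were weighed as tissue taken along with the organ. For Clps and Pla2g1b this is excluded, because the lower of their 2 stomach to pancreas ratios was 213 times the median ratio of the other enzymes. For the other 22 enzymes carry-over may hold and stays open: their median stomach level was 1.17% of that in pancreas, and 81.8% lay within 3 times of the median ratio in 1 stomach library but 77.3% in the other, under the 80% set beforehand and above the 50% that would have excluded it. A low level of these genes in stomach cells themselves was not tested.

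Marrow and muscle transcripts in spinal cord were weighed as tissue or reads from elsewhere. Circulating blood alone is excluded, because Mpo, Elane, Prtn3 and Ctsg, which promyelocytes of the marrow make, had 0.76 times the median ratio of the other neutrophil granule genes. Marrow taken with the cord may account for the blood cell transcripts: 82.35% of 17 neutrophil granule genes lay within 3 times of their median ratio, 1.55% of the bone marrow level, and the most abundant, Ngp and S100a9, stood at 164 ± 44.5 and 124 ± 3.95 CPM in spinal cord. Reads exchanged with the bone marrow libraries cannot be told apart from marrow taken with the cord for these genes. The test of that, a hippocampus to spinal cord quotient of 0.0 for the median ratios, excludes an exchange that reached hippocampus. It does not exclude one between marrow and spinal cord alone, which the bound set beforehand had overlooked. For the muscle transcripts such an exchange is excluded, because 11 of 11 muscle genes were higher in spinal cord than in bone marrow.

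The 9 genes between male and female over 7 tissues were compared with other labels. Of 64 ways to swap the sex labels within tissues, only the real one, 1 way, gave as many genes. The highest of the others gave 8, with the pancreas labels swapped. By the bound set beforehand, under 5% of the ways, this argues against chance for the count, by a narrow margin. It does not do so for each gene, and some of the 9 passed because of 1 tissue.

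Further results differed from the other tissues or appeared outside the gene tests. In liver the male over female fold of Hamp2 differed from that in the other 6 tissues by −7.02 ± 0.845 (log2, adjusted p = 0.0461). In pancreas that of Xist differed by 8.28 ± 0.895 (adjusted p = 0.00342), and it rests on 1 tag with 361 counts in the female and 554 in the male library. In parotid that of A2ml1 differed by 10.1 ± 1.01 (adjusted p = 0.00272), a fitted value that rests on 1 count in the female library against 1268 in the male one. Tags at genome positions without a gene took 11.963% of the female spinal cord library (exact 95% interval 11.929 to 11.998) against 2.74% of the male one. Tags without annotation took 18.565% of the female stomach library (18.522 to 18.608) against 4.18% of the male one. Tags read as reverse strand took 8.689% of the male spinal cord library (8.657 to 8.721), the highest of the 14. The unassigned tag GATCGTCGGACTGTAGAACT took 4.572% of the female stomach library (4.549 to 4.595), 0.556% of the male one and 0.0942% to 0.675% of the others; it resembles an adapter sequence, which was not tested.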

How the results depend on the processing

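Of the alternatives below, 5 were chosen only after the data were seen: without the stomach pair, tags of code 1 only, tags 1 base from a tag 50 times as abundant left out, tags with a run of 10 A left out, and the ratio centred on tag GC content. Of 6900 values of named genes under alternatives 6679 kept their direction and side of the threshold, 117 fell below it, 85 rose past it, 12 moved and 7 turned sign. The 7 were Reg2 over 7 tissues without the pancreas female (−1.15) or male (−1.14) library, where its main source is gone (without any other library its fold reached up to 6.596), Xist over 7 tissues with no tissue term (0.53), code 1 only (0.61) and the most abundant tag only (0.58), the last 2 of which keep mainly the tag abundant in pancreas, Spp1 in pancreas with library totals (−0.81) and Dnajc3 in parotid with the most abundant tag only (−0.041). The cause was not tested unless a sentence gives it. In what follows, counts of genes are those that passed.

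The TMM factors ran from 0.147 in the male pancreas library to 2.49 in the female spinal cord library. Library totals leave these factors out, and tissue counts then moved to 9176 in hippocampus, 10598 in pancreas, 4234 in parotid, 9972 in spinal cord and 7034 in pancreas against parotid. With limma voom they were 7592 in bone marrow, 6735 in liver, 3495 in pancreas, 3834 in parotid and 3406 in pancreas against parotid. Hippocampus against spinal cord gave 583 with code 1 only, 401 without single tags, 2206 on its own 4 libraries and 2202 without the stomach pair. Pancreas against parotid gave 1671 on its own 4 libraries and 1815 without the stomach pair.

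The sex difference over 7 tissues passed in 5 genes with DESeq2, 3 with limma voom, 5 at 10 CPM, 63 without a filter, 3 with no tissue term, 5 with code 1 only, 2 without single tags, 4 without the liver pair, 30 with the GC centring and 83 without the stomach pair. Within bone marrow it passed in 1 gene with DESeq2, 4 without a filter, 2 with the GC centring and 7 without the stomach pair. Within hippocampus it passed in 0 with DESeq2, limma voom, code 1 only or without single tags, 2 with DESeq2 size factors, library totals or runs of A left out, 3 without a filter or with the GC centring, and 4 without the stomach pair. In liver the counts were 25 with DESeq2, 8 with DESeq2 size factors or limma voom, 5 with library totals, 63 without a filter, 57 with the GC centring, 268 without the stomach pair, and 0 at 10 CPM, with code 1 only, without single tags or with the most abundant tag only. In pancreas they were 2 with DESeq2, 1 with library totals or the GC centring, 3 with limma voom, 4 without a filter and 7 without the stomach pair. In parotid they were 2 with DESeq2 or limma voom, 11 without a filter, 6 with the GC centring and 16 without the stomach pair. In spinal cord they were 0 with DESeq2, limma voom or without single tags, 2 with library totals or near-identical tags left out, 3 without a filter, 4 with the GC centring and 13 without the stomach pair. In stomach the GC centring gave 1814, with an interaction in 1416. Gene lists passed in 242 of 697 tests at the preset and in 79 with an estimated correlation. In fry 288 passed, and 215 of the 242 were among them. For 8 of the 242 the median fold had the sign opposite to the camera direction. The mean correlation of same-tissue pairs was 0.734 over all tags of at least 10 counts.

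Leaving out each library in turn, the counts ran from 3420 to 5530 in bone marrow, 4407 to 6643 in hippocampus, 2817 to 4930 in liver, 570 to 2202 in pancreas, 1005 to 3074 in parotid, 3632 to 5995 in spinal cord and 3029 to 5098 in stomach, where a lone library is assumed to vary like the other groups. They ran from 300 (without the spinal cord female) to 2230 (without the stomach male) for hippocampus against spinal cord, 439 (without the pancreas male) to 1868 (without the stomach female) for pancreas against parotid, and 9 to 119 (without the stomach female) for sex over 7 tissues. Within tissues sex gave 0 to 8 in bone marrow, 1 to 4 in hippocampus, 10 to 282 in liver, 0 to 12 in pancreas, 2 to 21 in parotid, 0 to 15 in spinal cord and 3410 to 3971 in stomach.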

Other observations

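The rise of secretory pathway genes in pancreas depended on the composition factor. In pancreas 14 of 23 endoplasmic reticulum genes rose against the other tissues, 15 adjusted over the list alone (camera adjusted p = 2.09e-08, and adjusted p = 0.0313 with an estimated correlation), while with library totals their median log2 fold was −1.29. In liver 10 rose and 1 fell (0.00326, but adjusted p = 0.124 with an estimated correlation). The list was lower in hippocampus, with 14 of 23 (4.10e-06, and adjusted p = 0.0305 with an estimated correlation), and in spinal cord, with 12 of 23 (1.34e-07, and adjusted p = 0.0195), where its median turned to 0.11 with library totals.

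Choroid plexus genes rose in hippocampus in 6 of 6 cases against the other tissues (camera adjusted p = 0.00215, and adjusted p = 0.0448 with an estimated correlation), at a summed 409.1 CPM in the female and 724.9 in the male library, with Enpp2 at 298.3 and 544.6. The list was not particular to hippocampus. Its sum was 466.3 CPM in female and 711.6 in male stomach, mostly from Clic6 (433.8 and 657.0). Enpp2 stood at 275.4 CPM in female and 261.5 in male spinal cord. Against spinal cord, 3 of 6 were higher, 5 adjusted over the list alone (4.29e-08, and adjusted p = 0.0174), beside the transthyretin described for that comparison. Immediate early and stress genes rose in stomach in 9 of 14 cases, 10 adjusted over the list alone (0.00340, but adjusted p = 0.0750 with an estimated correlation), and duct epithelium genes in 6 of 8, 7 adjusted over the list alone (0.000233, and adjusted p = 0.0471).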
